A study of Mus musculus with 2 samples.

How the data were processed

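The series held single-cell RNA profiles of the corticoseptal boundary of E16.5 mouse embryos, 1 library from WT and 1 from Tcf4f/f;Emx1Cre (Tcf4 cKO) embryos. Slices were dissected and enzymatically dissociated, and libraries were made per the labels with the 10x Genomics 3'v1 protocol, which tags the 3' end of transcripts. The deposited matrices hold raw UMI counts per gene and barcode with no normalization; they were made with Cell Ranger 7.1.0 per the file headers, whereas the submitters' processing notes name Cell Ranger 2.1.1 and mm10. The annotation release, the intron setting and the authors' own cell calls and cell types are not in the files, and the matrices include empty droplets. Gene positions came from GENCODE vM21, which held 32158 (99.6%) of the 32285 gene identifiers. CPM, ratios, log2 ratios and percents were all computed here from the deposited counts. Choices below were fixed before the data were examined unless said otherwise.

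A barcode was called a cell when its UMI total reached the percentile 99 of the 5000 largest totals in its library divided by 10, and at least 1000 UMIs. This set the limit at 3348 UMIs in WT, passed by 9166 of 2414768 barcodes, and at 3341 UMIs in cKO, passed by 10806 of 1872751. Cells needed at least 500 genes and at most 10% mitochondrial UMIs, which left 8964 WT and 10668 cKO cells. Doublets were called per library with scrublet in scanpy at an expected rate of 6% and removed, 330 in WT (3.68%) and 567 in cKO (5.31%). The remaining 8634 WT cells had medians of 9660 UMIs, 3389 genes and 2.80% mitochondrial UMIs, and the 10101 cKO cells had 8143 UMIs, 3042 genes and 3.19%. The cells held 79.2% of all UMIs in WT and 76.0% in cKO. Sex-linked genes made up 0.164% and 0.167% of UMIs, with Xist at 1569 and 1607 CPM and no Ddx3y UMI in either library.

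Free RNA was read from droplets of 10 to 100 UMIs. Its share of a neuron's UMIs was estimated from haemoglobin transcripts as 2.27% in WT and 1.19% in cKO. This estimate leaves out neurons with over 0.1% haemoglobin UMIs, a limit set after the data were seen and passed by 61 WT and 82 cKO cells of all kinds, since a first estimate over all neurons of 22.8% and 14.6% rested on a few cells that held red-cell RNA. Cells of both libraries were clustered together on log counts, 2000 variable genes and 30 principal components. Tcf4 and the sex-linked, mitochondrial, ribosomal and haemoglobin genes were left out of the variable genes. The graph joined 15 nearest neighbours by shared neighbours, a form of graph chosen after the data were seen, and Leiden clustering was run at resolution 1. The marker genes of each class were fixed beforehand, but the rules that turn them into names were not, and they were settled after the clusters had been seen. A marker counted when found in 20% of a cluster's cells and 1.5-fold over the rest, and at least 3 had to count. The class with the largest sum of log2 folds gave the name if that sum was 1.5 times the next one and no other class had more markers among the 10 leading genes. Clusters of low depth without a marker among those genes stayed unnamed, as did those named intermediate progenitor or glutamatergic neuron with Gsx1, Gsx2, Dlx1, Dlx2 or Dlx5 among them. Unnamed clusters, 29.3% of WT and 27.8% of cKO cells, stayed out of the classes.

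For each class, UMIs were summed per library. Levels are CPM with exact Poisson intervals, ratios (cKO over WT) have exact conditional binomial intervals, shares of cells have Clopper-Pearson intervals, all at 95%, and log2 ratios have a pseudocount of 5 CPM. With 1 library per group no test between genotypes exists, so no p-value was computed and cells were not treated as replicates. The median log2 ratio of each of 24 fixed gene lists, over members with at least 20 UMIs, was placed among 10000 random lists of the same size drawn from 20 expression bins, as a description only. Named genes had at least 50 UMIs, at least 50 CPM where higher, and a class level no lower than in free RNA. Mitochondrial, ribosomal, haemoglobin and sex-linked genes were left out, and genes were ranked by the bound of the ratio nearest to 1. The rule takes the 15 highest and 15 lowest in astroglia and in glutamatergic neurons, 5 and 5 in every other class with 100 cells per library, and 10 and 10 by the log2 ratio minus the GABAergic log2 ratio. For this choice, and for the differences printed, 0.5 was added to each UMI count in place of the pseudocount of 5 CPM, and the interval was a Wald interval; counts of genes past 1.5-fold used the pseudocount. It adds Tcf4 and any member of the fixed lists or ligand and receptor pairs. Some of the genes so chosen are not reported here. Ligand and receptor genes were compared at 20 CPM or more in either library. A cell counted as cycling when it held at least 2 UMIs of the G2 and M list and at least 0.5% of its UMIs in both cycle lists, the percent being set after the data were seen. For shares of cells with a UMI or cycling, each cell was thinned to 4000 UMIs, which left out 50 WT and 106 cKO cells.

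The ratio intervals and the ranking were tested on simulated data, Poisson draws from the mean profile of a class at the real library totals with 200 genes given known folds. The 95% interval held the true ratio for 95.6% of 11302 genes in astroglia and 95.7% of 11704 genes in glutamatergic neurons. All 30 top-ranked genes had a fold put in on purpose in each, and 5% and 4% of 200 random lists lay outside the central 95%. Such values follow from independent Poisson draws and random lists, so they check the computation only. The draws held no spread between cells or embryos and no genes that move together, as members of real lists may. Alternatives covered the UMI minimum, mitochondrial limit, doublets, cluster resolution, labels from WT clusters, free RNA, depth, cell weight, scaling, pseudocount and the count minimum for list members, and after the data were seen class membership and the weight of clusters were added. Software was Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.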

Results

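Single cells were profiled from the corticoseptal boundary of mouse embryos at E16.5, the midline tissue between cortex and septum through which callosal axons cross. The series held 1 wild-type (WT) library and 1 library from Tcf4f/f;Emx1Cre embryos (Tcf4 cKO), in which Cre driven by Emx1 acts in progenitors of the dorsal telencephalon. The WT library held 116998498 UMIs (unique molecular identifiers, each marking 1 captured transcript) and the cKO library 121321247. After filtering, 8634 WT cells with a median of 9660 UMIs and 10101 cKO cells with a median of 8143 UMIs remained. The labels do not say how many embryos made up each library. With 1 library per genotype there was no replicate check on any difference below: levels are UMI sums per class scaled to the class total (CPM), and every 95% interval (Poisson for a level, Clopper-Pearson for a share, conditional binomial for a ratio) covers counting error only.

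The first comparison asked where Tcf4, the bHLH E-protein transcription factor targeted in the mutant, was lower. Tcf4 (ENSMUSG00000053477, mm10 chromosome 18, 69343356 to 69689079) was lower in the cKO library in astroglia, cycling and intermediate progenitors and glutamatergic neurons, the 4 large classes that hold cells of the Emx1 lineage. Glutamatergic neurons held 2837 CPM (2812 to 2862) in WT and 1907 CPM (1887 to 1926) in cKO, a ratio of 0.672. Intermediate progenitors, the neuron-producing daughters of radial glia, held 2629 CPM in WT, with a ratio of 0.609 (0.594 to 0.624). Astroglia, the radial glia and astrocyte lineage, held 1778 and 1155 CPM, a ratio of 0.650 (0.634 to 0.666). In cycling progenitors the ratio was 0.666, and in Cajal-Retzius cells, the reelin-secreting neurons of the cortical surface, it was 0.358 (0.290 to 0.440). GABAergic neurons, which arise in the subpallium outside the Emx1 lineage, held 792 and 671 CPM, a ratio of 0.847 (0.824 to 0.872). The ratio was 0.937 (0.811 to 1.08) in oligodendrocyte progenitors, 0.802 in endothelial cells, 0.801 in microglia and 0.583 in the small class of ependymal or choroid plexus cells. Free RNA held Tcf4 at 977 CPM in WT and 711 CPM in cKO. The WT level of GABAergic neurons and of each of the smaller classes lay below the WT level in free RNA. The share of free RNA in neurons was estimated as 2.27% in WT and 1.19% in cKO. Within astroglia, Tcf4 differed by cluster. The ratio was 0.577 in cluster 9 and 0.623 in cluster 12, where Emx1 itself was present at 119 and 65.8 CPM in WT. In cluster 15, with 4.09 CPM of Emx1 and 281 CPM of the septal gene Six3 in WT, the ratio was 1.18 (1.09 to 1.28). Within glutamatergic neurons, the ratio was 0.716 in cluster 2, but Tcf4 was higher in cKO in cluster 8, at 1675 and 2099 CPM (ratio interval 1.17 to 1.34), and in cluster 22, with 17 WT cells and a ratio of 1.31. Because the labels do not give the floxed exon and the libraries count 3' tags, UMIs outside the deleted part say nothing about the remaining protein. The GABAergic difference had the opposite sign (log2 0.055) when the clusters of a class shared by both libraries were weighted equally, where the glutamatergic log2 ratio of -0.57 was -0.13; the astroglial log2 ratio of -0.62 was -0.26 at cluster resolution 0.5.

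**Figure D1:**
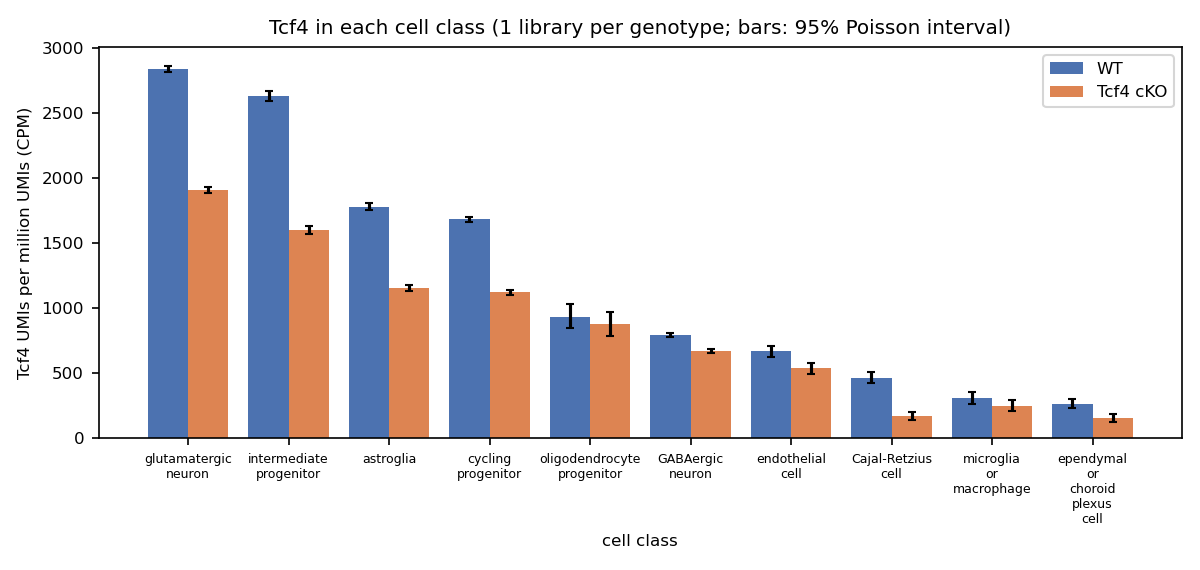
Tcf4 level in each named cell class (y axis, CPM) in the WT and the cKO library; error bars are exact 95% Poisson intervals. The cKO bar is lower in all 10 classes, from 2837 against 1907 CPM in glutamatergic neurons to 935 against 876 CPM in oligodendrocyte progenitors, whose intervals overlap. Those of microglia overlap too (266 to 353 and 208 to 290 CPM).

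The second comparison asked which cell classes each piece of midline tissue held. Glutamatergic neurons made up 18.9% (18.1 to 19.7) of WT cells and 23.2% (22.4 to 24.0) of cKO cells. Astroglia made up 9.67% (9.06 to 10.3) and 11.1% (10.5 to 11.7), and intermediate progenitors 7.29% and 7.96%. GABAergic neurons, by contrast, made up 19.0% (18.1 to 19.8) of WT cells and 15.9% (15.2 to 16.6) of cKO cells, and cycling progenitors 12.9% and 11.9%. The rules for naming clusters, set after the data were seen, left 29.3% of WT and 27.8% of cKO cells unnamed. Among these, the cells nearest to astroglia were 8.87% of WT and 4.33% of cKO cells, and those nearest to glutamatergic neurons were 3.23% and 6.60%. With the unnamed cells added to their nearest class, the astroglial share was lower in cKO by 3.13 percentage points (a difference of -3.13), in place of 1.42 points higher. The astroglial share was also lower in cKO with doublet calls kept in (-0.96) and with labels from WT clusters (-0.95). The same held at a lower (-3.415) and at a higher (-1.09) cluster resolution. It stayed higher with the UMI minimum doubled (1.12), with a stricter mitochondrial limit (0.78) and among neural cells only (1.38). Dissection and dissociation of a single library can set such shares, and the glutamatergic difference of 4.29 points ranged up to 8.10 and the GABAergic one of -3.05 from -4.78 to -0.18 over the alternatives.

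**Figure D2:**
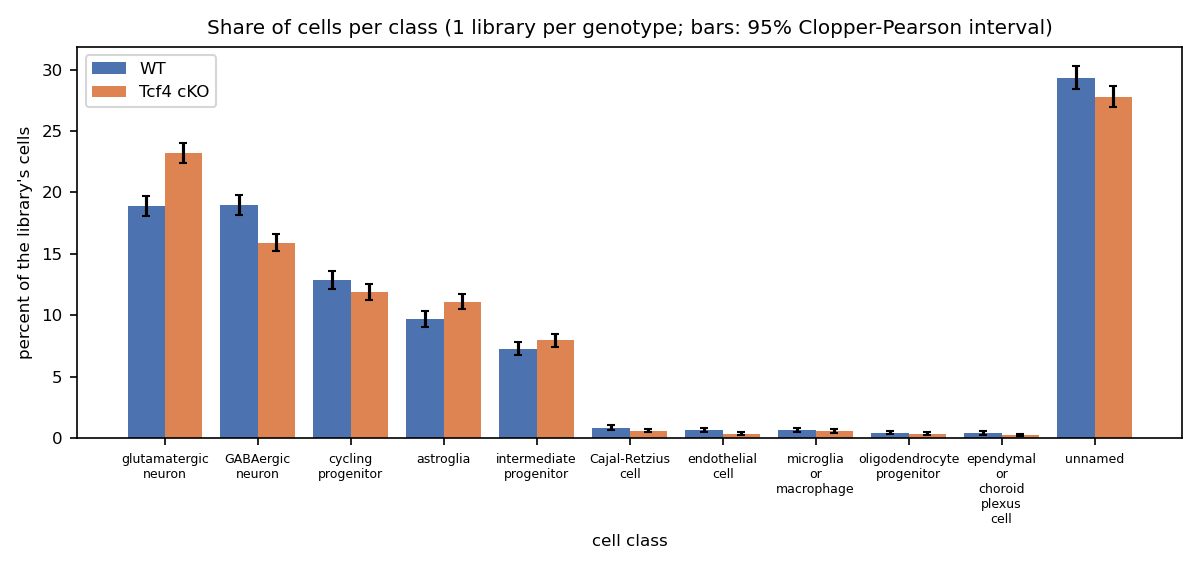
Share of each library's cells (y axis, percent) in each named class and in unnamed clusters, for WT and cKO; error bars are exact 95% Clopper-Pearson intervals. Glutamatergic neurons stand at 18.9% in WT and 23.2% in cKO, and GABAergic neurons at 19.0% and 15.9%.

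Glutamatergic neurons, the class to which neurons with callosal axons belong, were compared next. Callosal neurons were not set apart from the other neurons of the class. Nts, encoding the neuropeptide neurotensin, was 198-fold lower in cKO (104 to 433), at 92.5 CPM in WT and 0.468 CPM in cKO. Id2, an inhibitor of bHLH factors that binds E proteins, was 8.85-fold lower (8.40 to 9.32), and Cntn2, an axonal adhesion molecule, was 5.03-fold lower (4.74 to 5.35). Mef2c, a transcription factor of cortical neuron differentiation, was 3.37-fold higher (3.25 to 3.49), and Gas7, which binds actin in growing neurites, was 8.95-fold higher (7.45 to 10.8). Genes of axon guidance and growth lay on both sides. Lower in cKO were Sema6d at 3.45-fold, Plxna2, a semaphorin receptor, at 2.25-fold, Fgfr1, a fibroblast growth factor receptor, at 2.39-fold (2.26 to 2.52), and Nrp1, the neuropilin that binds class 3 semaphorins, at 1.90-fold. The cell-surface proteins Ntm, Opcml and Cadm2 were 2.60-fold, 2.28-fold and 2.54-fold lower. Higher in cKO were the ephrin receptor Epha3 at 2.55-fold (2.39 to 2.71), the adhesion molecule Negr1 at 2.55-fold, and Robo2, a Slit receptor, at 1.52-fold. The remaining named genes were Colec12, Trim9, Ebf1, St6galnac5, Arid5b, Atp1b1, Mir124-2hg, Sla, Kif26a, Dpy19l1 and Dok6 on the higher side, and Ppp1r14c, Syt4, Hs6st2, Schip1, Gt(ROSA)26Sor and Fabp3 on the lower. Colec12 stood at 0.512 CPM in WT and 110 CPM in cKO here and was also higher in every other group of cells tested.

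Gene lists fixed beforehand placed these genes in context. Of 24 lists, 10 had a median log2 ratio (cKO over WT) outside the central 95% of 10000 random lists matched on size and expression. The median of deep-layer corticofugal genes was 0.33, above all random lists, with 13 of 19 members higher, among them Etv1 (9.33 and 37.5 CPM), Foxp2 (23.6 and 54.9 CPM) and Rprm (61.4 and 122 CPM). Fezf2 and Bcl11b of the same list were lower, with ratios of 0.880 and 0.831. Upper-layer and callosal genes had a median of 0.14, also above all random lists, with 14 of 24 members higher, including Cux2 (ratio 2.82) and Pou3f2 (182 and 374 CPM). The FGF pathway had a median of -0.19 with 14 of 20 members lower, and cholesterol synthesis -0.15 with 17 of 19 members lower. Neuronal maturation genes had a median of -0.095 with 20 of 30 members lower. The remaining lists on the lower side were axon guidance receptors (-0.089), BMP and TGF-beta pathway (-0.10), midline glia genes (-0.090) and extracellular matrix (-0.084), and bHLH E proteins and partners lay on the higher side at 0.10. The bHLH list had the opposite sign under 6 alternatives, the midline list under 3, the upper-layer list (-0.020) when the UMI minimum for a cell was doubled, and axon guidance receptors (0.0050) with shared clusters weighted equally.

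Different clusters made up most of this class in each library. In WT, 681 neurons were in cluster 11, 467 in cluster 18 and 398 in cluster 2, whereas in cKO 808 were in cluster 2, 684 in cluster 8, 520 in cluster 17 and 324 in cluster 22. With 1 library per group, a cluster mostly of 1 library may be that library, not a type. Within cluster 2 alone, 26 of the 30 named genes differed in the same direction as in the whole class, 18 of them by at least 1.5-fold, and Nts, Syt4, Ntm and Opcml did not. Within cluster 8, with 66 WT cells, 24 of the 30 did, and Ebf1 (ratio 0.877), Syt4, Ntm, Hs6st2, Schip1 and Opcml did not. Some kept little more than the direction: the Gas7 ratio was 1.48 (0.926 to 2.44) in cluster 2 and 1.01 (0.360 to 3.92) in cluster 8, and in cluster 2 that of Fgfr1 was 0.846 and that of Cadm2 0.989. Syt4, Ntm, Opcml and Schip1 also had the opposite sign when the clusters shared by both libraries were weighted equally. In cluster 2, Nts rested on 2 WT and 4 cKO UMIs and Ntm on 6 and 12, too few to show a direction. In the unnamed cluster 5, nearest to this class (279 WT and 667 cKO cells), 29 of the 30 genes kept their direction, 26 by at least 1.5-fold. Opcml did not (ratio 1.34), and Nts had 79 and 2 UMIs. Cells of the 2 libraries lay apart in cluster 5 too, with 94.4% of nearest neighbours from the same library.

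**Figure D3:**
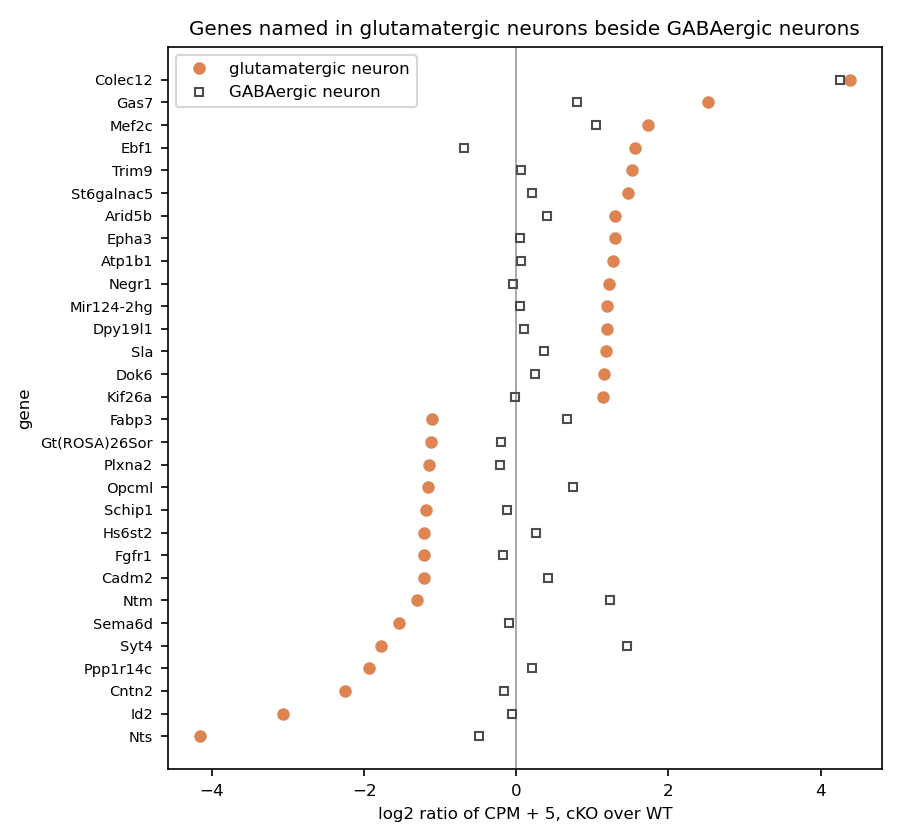
Log2 ratio of CPM plus 5 (x axis, cKO over WT) for the 30 genes named by rule in glutamatergic neurons (y axis, 1 gene per line), as filled circles, with the same genes in GABAergic neurons as open squares. Colec12 is high in both classes, whereas Nts, Id2 and Cntn2 lie far to the left only for glutamatergic neurons.

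Midline astroglia guide callosal axons and remodel the interhemispheric fissure. The named astroglia class, made of clusters 9, 12 and 15, gave smaller differences than the glutamatergic neurons. It leaves out the unnamed cluster 3 (766 WT and 437 cKO cells), nearest to astroglia and with Fgf17 and Fgf8 among its leading genes. In that cluster Id3 was 2.54-fold and Slc6a6 3.21-fold lower in cKO. What follows is about the named class only. Fgfbp3, a secreted carrier of fibroblast growth factors, was lower in cKO with a ratio of 0.641 (0.615 to 0.668), at 645 and 414 CPM. Tnc, the matrix glycoprotein tenascin C, was 1.58-fold lower (1.46 to 1.72), and Id3, a bHLH inhibitor induced by BMP signals, was 1.52-fold lower. Veph1 was 2.17-fold lower (1.86 to 2.52) and Ptx3, a secreted pentraxin, 1.90-fold lower. Aldh1l1, an astrocyte enzyme, was 1.60-fold lower, Mt3 1.43-fold and Cst3 1.34-fold, but the fixed list of astrocyte maturation genes had 12 members higher and 13 lower, with a median of -0.035 inside the random range. The metallothioneins Mt1 and Mt2, which bind zinc, were 1.80-fold and 1.49-fold higher. Neurog2, a proneural gene, was higher as well at 1.28-fold, and Eomes, a factor of intermediate progenitors, at 1.39-fold. Further named genes were Colec12, BC004004, Wdfy1, Alcam, Gm29260, Mpped2, Rhcg, Foxn3, Sfrp1 and Nrn1 on the higher side, and Tcf4, Plxnc1, Egr1, Lamtor3, Cntnap2 and Bcl2 on the lower.

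Of the 24 lists, 8 lay outside the central 95% of random lists in astroglia. Intermediate progenitor genes had a median log2 ratio of 0.33, above all random lists, with 11 of 12 members higher, such as Gadd45g at 46.1 and 67.7 CPM. Neuronal maturation genes had a median of 0.19 with 21 of 27 members higher, bHLH E proteins and partners 0.14 with 13 of 18 higher, and genes of the G2 and M phases 0.063 with 37 of 51 higher. Neuron transcripts at low level were part of this, with Neurod2 at 7.22 and 18.3 CPM and Tubb3 with a ratio of 1.45. The G2 and M median can depend on the border of the class, since cells with strong cycle markers had been named a class of their own. Cholesterol synthesis had a median of -0.22, below all random lists, with 18 of 19 members lower, such as Msmo1 (215 and 173 CPM) and Insig1 (100 and 81.6 CPM). The FGF pathway had a median of -0.11 with 13 of 22 members lower, including the feedback inhibitors Spry1 (24.1 and 16.6 CPM) and Spry2 (42.2 and 31.3 CPM). Radial glia genes had a median of -0.099 with 14 of 21 lower, among them Id4 (406 and 300 CPM) and Ptprz1 (997 and 825 CPM), and extracellular matrix genes -0.066 with 25 of 38 lower. The list of midline glia and interhemispheric remodelling genes had 16 of 22 members lower, but its median of -0.037 lay inside the random range of -0.067 to 0.048. The glial transcription factors Nfia (779 and 772 CPM) and Sox9 (572 and 550 CPM), and the protease gene Mmp14 (72.9 and 70.1 CPM), differed little, with ratios of 0.991, 0.960 and 0.961. Astroglia lay in clusters 9 (290 WT and 407 cKO cells), 12 (280 and 401) and 15 (265 and 312). Of the 30 named genes, 29 kept their direction within cluster 9, 30 within cluster 12 and 22 within cluster 15. The other 8 in cluster 15 were Tnc, there 2.88-fold higher (1.73 to 5.02), Id3, 1.32-fold higher, Tcf4, Egr1 and Fgfbp3, and, lower there, Mt2, Alcam and Mpped2. With the unnamed cells added to their nearest class, 18 lists lay outside the random range in place of 8.

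Intermediate progenitors and cycling progenitors stand between radial glia and neurons. In intermediate progenitors Pou3f1, a factor of upper-layer neurons, was 2.86-fold higher in cKO (2.49 to 3.29) and Sema5a, a semaphorin, 2.73-fold higher. Flrt1 was 3.87-fold lower (3.24 to 4.64), Prmt8 2.76-fold, Txnip 2.72-fold, Rprm 2.22-fold and Tesc 2.21-fold lower. Colec12 (1 UMI in WT, ratio 535, 95.6 to 21172), BC004004 and Alcam completed the higher side. Upper-layer genes had a median of 0.23 with 18 of 21 members higher, above all random lists, and S-phase genes had a median of -0.19 with 28 of 37 lower, such as the replication helicase gene Mcm6 (46.8 and 18.9 CPM). Cells with strong cycle markers had been named a class of their own, so the S-phase median can depend on where that border fell. In all, 11 of 24 lists lay outside the random range, the others higher being intermediate progenitor genes (0.13), neuronal maturation (0.077) and hypoxia and glycolysis (0.056). Those lower were midline glia (-0.18), extracellular matrix (-0.16), astrocyte maturation (-0.15), BMP and TGF-beta (-0.14), cholesterol synthesis (-0.12) and immediate early genes (-0.11). In cycling progenitors, Mt1 was 3.01-fold higher (2.84 to 3.19), Mt2 2.11-fold and Tagln2 1.66-fold, with Sfrp1 and Alcam next. Fgfbp3 was 2.05-fold lower (1.93 to 2.18), Neurod1 1.82-fold, Rprm 1.73-fold, and Elavl2 1.54-fold lower, and Tcf4 had a ratio of 0.666 (0.653 to 0.679). Intermediate progenitor genes had a median of -0.30 in cycling progenitors, with 11 of 15 members lower, and 13 of 24 lists lay outside the random range. Cluster 19, with Eomes, Neurod4 and Insm1 among its leading genes, held 268 of the 1110 WT and 175 of the 1201 cKO cycling progenitors, so the make-up of the class differed in the direction of this median. Cycling progenitors were not recomputed under the alternatives. The count in intermediate progenitors was 6 lists with cells thinned to 1 depth, where the neuronal maturation median had the opposite sign (-0.025).

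GABAergic neurons served as a class from outside the Emx1 lineage in the same libraries. Kctd12 was 4.19-fold higher in cKO (3.59 to 4.90), and Lhx6, a factor of interneurons from the medial ganglionic eminence, was 3.32-fold higher. Syt4 was 2.89-fold higher, Ptprd stood at 53.9 and 108 CPM, and Colec12 was 274-fold higher (117 to 845). The class lay in different clusters in each library: Lhx6 and Syt4 are among the leading genes of cluster 26, with 22 WT and 151 cKO cells, and cluster 1 held 674 and 539. Calb2, the calcium-binding protein calretinin, was 2.26-fold lower (2.08 to 2.46), with Otx2, Hrk, Ccnd2 and Sox2ot at 1.58-fold, 1.58-fold, 1.38-fold and 1.38-fold lower. Here 13 of 24 lists lay outside the random range. Midline glia genes had a median of -0.17 with 18 of 23 members lower, and Wnt pathway genes -0.12. Radial glia genes (-0.096) and extracellular matrix genes (-0.099) lay below the random range as they did in astroglia (-0.099 and -0.066). Their lower medians were thus not particular to astroglia. Neuronal maturation had a median of 0.17 with 23 of 28 members higher, upper-layer genes 0.13 and deep-layer genes 0.097. Cholesterol synthesis lay inside the random range in this class, with a median of 0.044 and 14 of 19 members higher. Genes were also chosen by the log2 ratio minus the GABAergic log2 ratio, which fixes that their difference is large; the differences given here add 0.5 to each UMI count in place of 5 CPM. The 20 so chosen in glutamatergic neurons were all past 1.5-fold with 5 CPM added, led by Ebf1 (difference 2.63) and Gas7 (2.09) and by Nts (-4.96) and Syt4 (-3.45). Of the 20 so chosen in astroglia 14 were past 1.5-fold, among them Samd4 (1.11), Mt1 (1.01), Ddah1 (-1.19) and Mt3 (-0.90). At cluster resolution 0.5 the astroglial count was 4 and 8 GABAergic lists lay outside the random range. With shared clusters weighted equally the gene counts were 12 and 5, 7 GABAergic lists lay outside, and the GABAergic medians of the radial glia, Wnt, upper-layer and cell adhesion lists had the opposite sign.

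**Figure D4:**
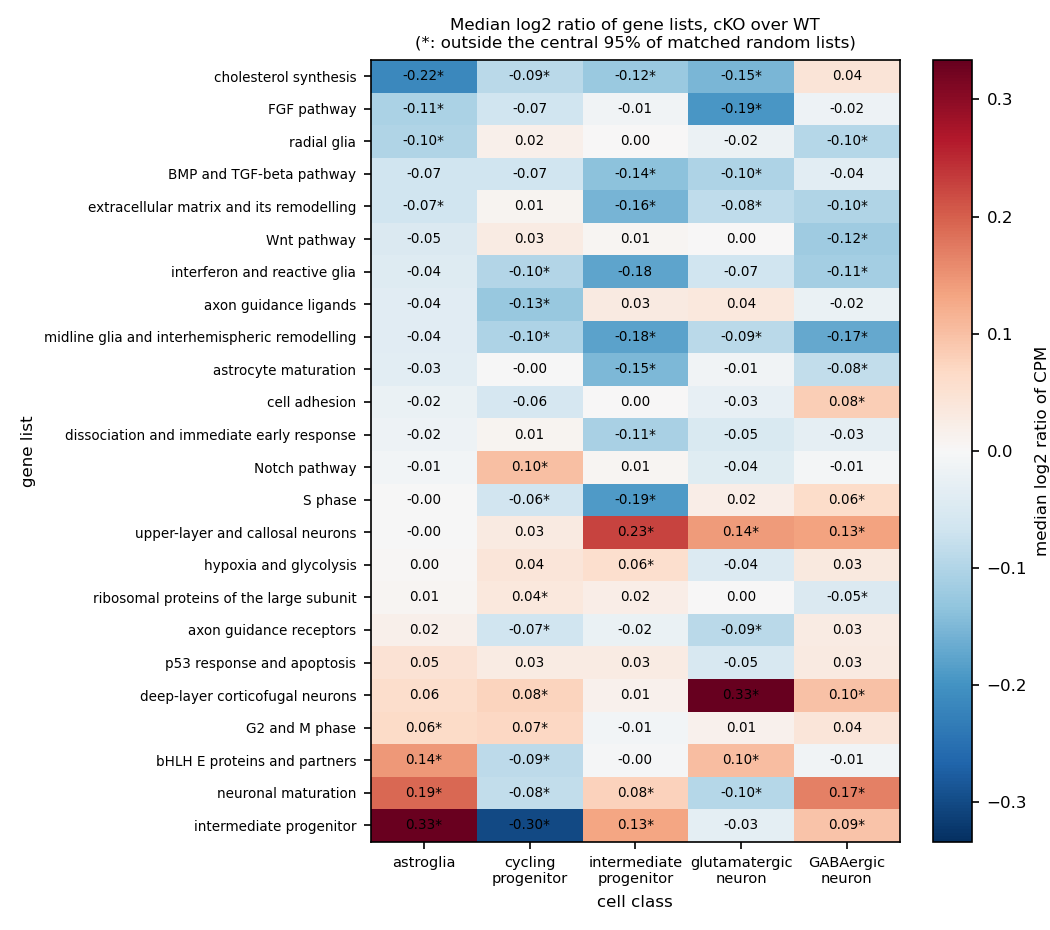
Median log2 ratio of CPM (cKO over WT, colour and printed value) of each of the 24 gene lists (y axis) in 5 cell classes (x axis); an asterisk marks a median outside the central 95% of matched random lists. Intermediate progenitor genes stand at 0.33 in astroglia and -0.30 in cycling progenitors, and cholesterol synthesis at -0.22 in astroglia against 0.04 in GABAergic neurons.

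The next comparison took up the neuron-astroglia communication that the title of the series names, through fixed ligand and receptor pairs. Most of the measured genes differed by less than 1.5-fold. In astroglia, 1 of 55 genes at 20 CPM or more was at least 1.5-fold higher in cKO, Sema5a (27.1 and 48.1 CPM), and 2 were lower, Tnc and Adgrl3, a latrophilin (44.9 and 26.3 CPM). In glutamatergic neurons 6 of 56 were higher, namely Cadm1, Dner, Fgf13, Negr1, Ptn and Robo2, and 6 were lower, namely Epha5, Fgfr1, Nectin3, Nrp1, Plxna2 and Tgfb2. Ptn, the growth factor pleiotrophin, was at 239 and 404 CPM in the neurons, a ratio of 1.69 (1.63 to 1.76), while its receptor Ptprz1 in astroglia had a ratio of 0.827 (0.802 to 0.852). Fgfr1 in the neurons had a ratio of 0.419, with its partner Ncam1 at 274 and 282 CPM in astroglia. Sema6a in astroglia had a ratio of 0.736 and its receptor Plxna2 in neurons 0.444. The ephrin receptor Epha5 in neurons had a ratio of 0.542 (0.526 to 0.559), and its ligand Efna5 in astroglia 0.910. Slit2 in astroglia had a ratio of 1.01, with Robo2 in neurons at 1.52. RNA levels of a pair say nothing on contact or signalling, and the total of 15 genes was 26 with shared clusters weighted equally.

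The last comparison asked how many astroglia and progenitors were cycling. With each cell thinned to 4000 UMIs, 56.4% (54.5 to 58.3) of WT and 53.5% (51.8 to 55.3) of cKO cells carried cell-cycle transcripts above the limit, and 55.7% and 53.3% did without thinning. Shares within a single class are not given, because cells with strong cycle markers had already been named a class of their own. Glutamatergic neurons, which do not divide, gave a background of 0.799% and 0.559% at median depths of 10010 and 7599 UMIs before thinning, against 9548 and 7596 UMIs in intermediate progenitors. Thinning left out 5 WT and 10 cKO astroglia, 2 and 3 intermediate progenitors, 4 and 5 cycling progenitors, and 5 and 17 glutamatergic neurons. The pooled difference of -2.89 percentage points had the opposite sign under 4 alternatives, with values from 0.234 to 3.31 points.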

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

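Both comparisons of this part were chosen only after the results were seen, since they were set up once the tables of the libraries had been read. Droplets of 10 to 100 UMIs, which hold free RNA and not cells, served elsewhere only as the profile of free RNA. In these droplets haemoglobin genes made up 1.18% of UMIs in the cKO library (1.17 to 1.20), above the 0.749% in the WT library (0.738 to 0.760). Mitochondrially encoded genes made up 7.48% of the UMIs of such droplets in the cKO library (7.45 to 7.51), above 7.25% in the WT library (7.22 to 7.28). Both shares were picked out because they exceeded the WT library by more than counting error, and the difference between the libraries was not tested further.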

How the results depend on the processing

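Results in astroglia, glutamatergic neurons, intermediate progenitors and GABAergic neurons, the ligand and receptor counts and the pooled cycling share were recomputed. The lists, named genes, Tcf4 and share of cycling progenitors, and Tcf4 and shares in the smaller classes, were not. The alternatives were chosen before the data were examined, except 3 chosen after seeing the data: unnamed clusters put in their nearest class, clusters of a class with at least 20 cells in each library weighted equally, and named genes recomputed within single clusters. No paired analysis was possible because there was 1 library per group, and no result came from a test. Of the main results, 125 values under an alternative stayed close to the reported one, 54 moved and 10 reversed. For list medians the counts were 1110, 213 and 21, and for named genes 693, 343 and 4. These labels rest on a tolerance that is not given here, so a value counted as close can still differ from the reported one. By these labels median-of-ratios scaling and a pseudocount of 1 CPM moved no main result, but a pseudocount of 1 CPM moved 10 list medians and 8 named genes. Unless said otherwise the cause was not tested. In the reported setting the log2 ratio of Tcf4 was -0.62 in astroglia, -0.57 in glutamatergic neurons, -0.71 in intermediate progenitors and -0.24 in GABAergic neurons. Counts were low in rare classes: the Tcf4 ratio of oligodendrocyte progenitors, from 426 and 353 UMIs, spanned 0.811 to 1.08.

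With the UMI minimum for a cell doubled, the Tcf4 log2 ratio was -0.52 in astroglia, -0.60 in glutamatergic and -0.29 in GABAergic neurons, 9 of 20 named genes of astroglia differed from the GABAergic ratio by 1.5-fold in the named direction, and the difference in cycling share reversed to 3.31 points. Medians that reversed were those of upper-layer genes (-0.020) and bHLH E proteins (-0.060) in glutamatergic neurons and of intermediate progenitor genes in GABAergic neurons (-0.015). With at most 5% mitochondrial UMIs, 13 astroglial lists lay outside the random range, Tcf4 was at -0.61 in glutamatergic neurons, -0.75 in intermediate progenitors and -0.18 in GABAergic neurons, and the glutamatergic share differed by 7.13 points.

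With doublet calls kept in, Tcf4 was at -0.40 in astroglia, -0.76 in intermediate progenitors and -0.28 in GABAergic neurons, with 17 astroglial and 8 GABAergic lists outside. The share differences were 7.06 points in glutamatergic and -0.18 in GABAergic neurons, and reversed in astroglia (-0.96) and for cycling cells (0.23). The glutamatergic medians of midline glia genes (0.016) and bHLH E proteins (-0.0020) and the GABAergic median of astrocyte maturation (0.087) reversed as well.

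At cluster resolution 0.5, Tcf4 was at -0.26 in astroglia, -0.76 in intermediate progenitors and -0.285 in GABAergic neurons. The lists outside numbered 18 in astroglia, 6 in intermediate progenitors and 8 in GABAergic neurons, and 4 named genes of astroglia differed so from the GABAergic ratio. The shares differed by 8.10 points in glutamatergic and -4.78 in GABAergic neurons, and reversed in astroglia (-3.415) and for cycling cells (1.58), as did the glutamatergic bHLH median (-0.033). At resolution 2.0, Tcf4 was at -0.38 in astroglia, -0.55 in glutamatergic and -0.32 in GABAergic neurons, with 16 astroglial lists outside. There the shares differed by 7.94 points in glutamatergic and -0.49 in GABAergic neurons, reversed in astroglia (-1.09), and the glutamatergic bHLH median was -0.0097 (reversed).

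With labels passed from WT clusters, Tcf4 was at -0.40 in astroglia and -0.14 in GABAergic neurons, 13 astroglial lists lay outside and 7 named genes of astroglia differed so from the GABAergic ratio. The shares differed by 7.63 points in glutamatergic neurons and reversed in astroglia (-0.95), as did the glutamatergic bHLH median (-0.034) and the GABAergic cell adhesion median (-0.027). With the ambient profile subtracted, the GABAergic median of astrocyte maturation reversed to 0.020. With cells thinned to 4000 UMIs, Tcf4 was at -0.55 in astroglia and -0.54 in glutamatergic neurons, 6 lists of intermediate progenitors lay outside and their neuronal maturation median reversed to -0.025. That median was -0.0019 with list members of at least 100 UMIs, where fewer genes entered it. With the mean of per-cell CPM, Tcf4 was at -0.56 in astroglia and -0.55 in glutamatergic neurons.

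With unnamed clusters put in their nearest class, which by construction adds 766 WT and 437 cKO cells to astroglia, the astroglial share reversed to -3.13 points. Tcf4 was then at -0.27 in astroglia, -0.55 in glutamatergic neurons, -0.63 in intermediate progenitors and -0.13 in GABAergic neurons, with 18 astroglial lists outside. The shares differed by 7.67 points in glutamatergic and -1.33 in GABAergic neurons, and the cycling share (0.56) and the glutamatergic medians of midline glia genes (0.0040) and bHLH E proteins (-0.021) reversed. With shared clusters weighted equally, which by construction leaves out the glutamatergic clusters 11, 17, 18 and 22, Tcf4 was at -0.58 in astroglia and -0.13 in glutamatergic neurons and reversed to 0.055 in GABAergic neurons. There 7 GABAergic lists lay outside, 5 astroglial and 12 glutamatergic genes differed so from the GABAergic ratio, and 26 ligand and receptor genes differed by 1.5-fold. Reversed log2 ratios in glutamatergic neurons were those of Syt4 (0.13), Ntm (0.29), Schip1 (0.23) and Opcml (0.95) and the medians of midline glia genes (0.030) and axon guidance receptors (0.0050). In GABAergic neurons the medians of radial glia (0.032), Wnt (0.025), upper-layer (-0.052) and cell adhesion (-0.033) genes reversed.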

Other observations

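The tests of UMI depth in glutamatergic neurons and of free RNA were set before their values were seen; the other 9 tests of this part, and the clusters and genes it names, were chosen only after; among these the test of Fgf17 levels took the place of one on the share of cells with Fgf17, written before its value was seen, and of one on the share with Rsph1, since both shares belong to the pattern itself. Cells left without a class also differed between the libraries. In cluster 5, nearest to glutamatergic neurons, cells of the 2 libraries lay apart, with 94.4% of nearest neighbours from the same library. There Cck, the neuropeptide cholecystokinin, was 33.0-fold lower in cKO (26.8 to 41.1), Calb1, the calcium-binding protein calbindin, 27.4-fold lower (18.1 to 43.3), Id2 19.5-fold lower and the somatostatin receptor Sstr2 18.5-fold lower. Rgs4, a regulator of G-protein signalling, was 11.1-fold higher (7.67 to 16.6), and Rprm was 4.70-fold higher. Cluster 3, nearest to astroglia, had 395 CPM of Six3 in WT and 358 CPM in cKO. In this cluster Id3 was 2.54-fold lower (2.27 to 2.84), Id1 2.56-fold, the taurine transporter gene Slc6a6 3.21-fold and the growth factor binding protein gene Igfbp5 1.95-fold lower, and Sfrp1, a secreted Wnt antagonist, was 1.60-fold higher (1.44 to 1.78). Single genes of the immediate early response were among the lowest too, Egr1 at 1.89-fold lower in cluster 3 and Fos at 2.05-fold and Jun at 1.76-fold lower in cluster 21; the fixed list of that response was not computed in these clusters, and its median lay inside the random range in astroglia (-0.018), glutamatergic neurons (-0.050), GABAergic neurons (-0.030) and cycling progenitors (0.0079) and below it in intermediate progenitors (-0.11). Fos stood at 531 and 410 CPM over all cells and at 280 and 281 CPM in GABAergic neurons, so a difference in dissociation response is not excluded as part of these values. The Tcf4 ratio in cluster 3 was 0.953 (0.902 to 1.01).

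Across 6256 genes, log2 ratios of different classes were compared by correlation, in which genes are not independent replicates. Pearson's r was 0.42 (Spearman's rho 0.33) between intermediate and cycling progenitors, 0.38 (0.35) between glutamatergic neurons and intermediate progenitors, and 0.25 (0.28) between astroglia and glutamatergic neurons. With GABAergic neurons r was 0.095 (rho 0.0036) for glutamatergic neurons, 0.12 (0.056) for astroglia, 0.13 (0.061) for intermediate and 0.19 (0.13) for cycling progenitors. The value that shared libraries alone would give was not derived.

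Glutamatergic neurons of the 2 libraries lay apart in expression space: 89.6% of their nearest neighbours came from the same library. Depth is argued against, since 85.9% were still from the same library after thinning to 4000 UMIs, and a library-wide batch or free RNA was argued against by GABAergic neurons of the same libraries, at 53.9%, although clusters 7 and 23, nearest to subpallial neurons, reached 61.4% and 67.5%. A more lateral piece of pallium in the cKO dissection stays open. In astroglia a list of lateral pallial genes lay above all random lists (median 0.20), while a list of medial genes lay at percentile 78.1. In intermediate progenitors the lateral list was higher too (0.40, with 9 of 9 members higher) and the medial list lay at percentile 68.8. In GABAergic neurons both lists were low (-0.146 and -0.143). In the glutamatergic neurons themselves both were high (0.51 and 0.13), with 6 of 9 lateral and 6 of 11 medial members higher. The medial list there goes against the lateral explanation. The bound first set looked at the medial list alone and would have spoken against it, but was set aside because the lateral list moved as this explanation needs. Loss of Tcf4 may also contribute, since the lowest share among the other classes of the Emx1 lineage was 57.6%. That share was above the GABAergic one though below clusters 7 and 23. Genotype and library are the same split, so neither explanation can be told apart from the other. The cKO genotype also carries Emx1Cre. Emx1 itself was lower in cKO, with ratios of 0.682 in glutamatergic neurons, 0.659 in intermediate progenitors, 0.695 in cycling progenitors and 0.823 in astroglia. An effect of the Emx1Cre allele was not tested and cannot be told apart either.

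Only Colec12, BC004004 and Rpl29, of 8149 genes tested, differed by at least 0.5 in log2 in the same direction in all 12 groups of cells. Colec12, a scavenger receptor gene, stood at 4.36 CPM in WT and 88.7 CPM in cKO over all cells, BC004004 at 33.0 and 166 CPM, and the ribosomal protein gene Rpl29 at 979 and 1696 CPM. Free RNA of the cKO library, with its share corrected after a first estimate was seen, accounted for at most 1.45% of the lowest class level of these genes. The log2 ratio in GABAergic neurons was at least 94.1% of that in glutamatergic neurons for each gene. A GABAergic difference of at least 0.5 was fixed by how the genes were chosen, so for Rpl29 (0.730 and 0.765) the test could hardly come out otherwise. For Colec12 and BC004004 the GABAergic log2 ratios of 4.26 and 1.94 lay far above that minimum. There they argue against loss of Tcf4 inside the cell. Sequence carried along with the floxed allele is argued against for BC004004 and Rpl29, of which 0 lie on chromosome 18 with Tcf4. For Colec12, on chromosome 18 at 59.6 Mb from Tcf4, it cannot be told apart from a difference in strain background elsewhere, which was not tested.

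Cells with UMIs of Fgf17 and Fgf8, growth factors of the rostral midline, were fewer in the cKO library: with cells thinned to 4000 UMIs, 3.27% (2.91 to 3.67) of WT and 1.28% (1.07 to 1.52) of cKO cells held an Fgf17 UMI and 4.22% and 1.77% an Fgf8 UMI, against 0.433% and 0.254% for Fgf17 in GABAergic neurons, whose median depths were 8336 and 7515 UMIs. Lower Fgf levels may be a part of this: inside cluster 3 the ratio was 0.537 for Fgf17 (228 and 123 CPM) and 0.759 for Fgf8. Other leading genes of cluster 3 were found in fewer cells too. Shares of all thinned WT and cKO cells were 5.01% and 3.20% for the cilium gene Rsph1 (1.67% and 1.33% in GABAergic neurons) and 5.49% and 3.42% for Foxj1 (1.30% and 0.824%). They were 3.36% and 2.30% for Ogn and 1.68% and 0.920% for Cnmd. Inside cluster 3 neither Rsph1 (130 and 131 CPM) nor Foxj1 (131 and 153 CPM) was lower. The Rsph1 and Foxj1 shares are part of the pattern itself, and Ogn and Cnmd were picked as leading genes of cluster 3. These genes also helped to set that cluster, so their levels inside it are no independent check. Lower Fgf levels in as many cells therefore cannot be told apart from fewer cells by these values. Less septal tissue stays open: the unnamed clusters 4 and 23, nearest to septal or subpallial projection neurons, had ratios of 1.21 and 0.588, on either side of 1, where a first form of the test had pooled them (1.06). The Tcf4 ratio was 0.953 (0.902 to 1.01) in cluster 3 and 0.874 (0.810 to 0.942) in cluster 21. In the astroglial clusters 9 and 12, which held more Emx1, it was 0.577 and 0.623 from the same 3' tags. A fall of the tags as large as in clusters 9 and 12 was thus not seen in clusters 3 and 21. Whether Tcf4 was lost in the cells of clusters 3 and 21 cannot be told, since the tags may lie outside the unknown floxed exon. Tcf4 was also higher in cKO in the glutamatergic clusters 8 and 22, so the tags need not fall in this lineage. Clusters 3 and 21, which both have Fgf17 and Fgf8 among their leading genes, held 8.87% and 2.80% of WT cells. In cKO they held 4.33% and 1.72%, though these genes took part in setting the clusters. Fewer cells of this kind is a hypothesis, and 1 dissection per genotype could give it.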
